A study of Homo sapiens with 12 samples.

How the data were processed

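The samples were NCI-H1944 cells, a human lung adenocarcinoma line, from which double-stranded RNA had been collected with the J2 antibody and sequenced. Cells labelled SCR had a wild-type genotype and cells labelled IFNAR1sg had an IFNAR1 knockout genotype. The labels describe treatment with the MPS1 inhibitor BAY-1217389 (MPS1i) at 100 nM for 48 h, with DMSO as its control, or with recombinant interferon beta (IFNb) at 5 ng/ml. The drug was washed out after 48 h, and IFNb was given in the 24 h of culture that followed. The 6 groups of genotype and treatment had 2 libraries each, 12 in all. Input RNA was not analysed here, so a change in a J2 library can reflect the amount of a transcript, its double-stranded share or both. The libraries had been made with a stranded total RNA kit and converted for DNBSEQ sequencing.

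The deposited table holds counts, whole numbers of reads per stranded genomic region, not normalized. The submitters' processing notes name Trim Galore, Trimmomatic, cutadapt, STAR, featureCounts and HOMER without versions or roles, and give the builds GRCh38 and hg38. How strands, overlaps and reads that map to several places were counted is not given in the sources used here. The table has 5254113 regions that do not overlap on a strand, with a median length of 139 bp; 46.1% had 0 reads in all 12 libraries. It names the repeats that lie in a region. Regions were placed against the GENCODE annotation of hg38, in which 58252 of 58780 gene identifiers were matched to a current symbol. A region was called intronic when it lay in a gene on the gene's strand without sharing an exon base, antisense when a gene lay only on the other strand, and intergenic when no gene overlapped it. The 19287 regions that shared at least 1 base with an exon of their strand formed a class of their own (exon-sharing). They held 37.2% of reads, and 14210 of them shared at most 2 bases yet held 34.1% of reads, 884 reads per kb against 24.9 in regions sharing no exon base. Most reads of the exon-sharing class thus lay in regions sharing at most 2 bases with an exon. A value for such a region can stand for reads of the adjoining exon as well as for the region. Whether the table holds all exonic reads is not known.

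Regions were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit, glmQLFTest), with TMM factors and filterByExpr by group (minimum count 10, minimum total 15, proportion 0.7), which left 89111 regions. All 12 libraries were fitted together with 1 coefficient per group, which left 6 residual degrees of freedom; the common dispersion was 0.0313 and the prior degrees of freedom were 72.8. A region was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold limit. The contrasts were MPS1i minus DMSO and IFNb minus DMSO within each genotype, IFNAR1sg minus SCR in DMSO, and for each treatment the interaction, coded as the change in SCR minus the change in IFNAR1sg. Changes are given as log2 fold changes ± standard error with n = 2 libraries per group, and levels as CPM (counts scaled to the library size) scaled by TMM. The standard error was taken as the size of the change divided by the square root of its F value, which is unreliable where a change is near 0.

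Counts were also summed per gene (regions on the strand of a single gene), per repeat subfamily and per repeat family (regions with exactly 1 repeat name, which held 21.2% of reads). These sums left out the exon-sharing regions, a choice made after the structure of the table was known and before any test. With the library sizes and factors of the region fit kept, 15213 gene sums, 1653 subfamily sums and 56 family sums were tested in the same way. A gene sum is thus mostly intronic reads. A repeat sum follows the transcripts that carry the repeats.

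Before the data were examined, 14 gene lists and 34 repeat lists were fixed, together with the contrasts, the alternatives and the rule for naming features. The gene lists were interferon-stimulated genes, double-stranded RNA sensing and processing, DNA sensing, antigen presentation, NF-kB targets and cytokines, p53 targets, mitosis and cell cycle, the unfolded protein and integrated stress responses, replication-dependent histones, structured small RNAs, mitochondrially encoded genes, and markers of lung epithelium, fibroblasts and immune cells. The repeat lists were Alu (with AluJ, AluS and AluY), L1 (with young L1), L2, MIR, SVA, ERV1, ERVK, ERVL, ERVL-MaLR, LTR12, HERV9, MER41, MER57, LTR10, THE1, MLT1, MLT2, HERVH with LTR7, HERVK with LTR5, HERVE with LTR2, alpha satellite, HSATII, other satellites, DNA transposons, simple repeats, rRNA, tRNA, 7SL-like, snRNA and scRNA. No region had HSATII or rRNA as its single repeat name, and no mitochondrially encoded gene or structured small RNA was measured as a gene sum. Lists with at least 3 measured members, 41 in all, were tested with camera of limma 3.58.1 on log CPM (prior count 2, preset correlation 0.01), with an estimated correlation and fry beside it, and Benjamini-Hochberg adjustment over the lists. List tests were planned for both treatments in SCR and for the interactions; those for the treatments in IFNAR1sg were added later. Counts of list members past the threshold are given after adjustment over all gene or subfamily sums and adjusted over the list alone.

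The named regions were, for each contrast but IFNb in IFNAR1sg and the genotype contrast, the 12 higher and 12 lower with the smallest p among called regions whose treated libraries both lay beyond both control libraries (for an interaction, the SCR libraries), with 1 region per gene and per 10 kb. The rule also took up to 6 repeat sums per direction, up to 4 members per list, and IFNAR1, IFNB1, CXCL10, ISG15 and CDKN1A. Some of the results chosen this way are not reported here. The test was tested on simulated data by changing 200 of 89111 regions: between 8.96% and 11.9% of regions changed by 1 on the log2 scale were called and between 36.4% and 51.5% of those changed by 2, with 0 to 5 false calls among 31 to 42. A changed set was called by camera and 0 of 20 random sets were. Precision therefore limits what could be seen, though these shares were not split by count. With so few regions changed the adjusted threshold is stricter than where many change, so the shares are not the sensitivity of contrasts with many calls. Values after ± cover counting and replicate error only, unless given as an SD. Intervals of medians were drawn by resampling genes or regions, and that of the ratio of shares past gene ends treats regions as independent, so these intervals leave out the spread between the 2 libraries of a group. For a test of strands, antisense regions called higher in one genotype were measured in the libraries of the other, against the summed reads of all regions overlapping them on the other strand, where these averaged at least 10 reads per library. Library sizes were also set to antisense totals.

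The labels number replicates but do not say that they were separate cultures, so p-values measure the spread between these libraries, which may be technical. Over all 12 libraries the replicates of each group differed by more than sampling noise (chi-square per region 1.95 to 3.29). Residuals correlated above 0.1 by replicate number in 6 of 15 pairs of groups (median 0.0750, 17595 regions), so the replicate number was tried as a block and not used in the reported fit. The alternatives planned were DESeq2 size factors in the edgeR fit, library totals with no TMM factor, no filter, a filter on a mean of 10 counts, the Wald test of DESeq2 1.42.0, only the groups of a contrast, a replicate block, a log2 fold limit of 1, and leaving out each library. Added after seeing the data were only regions sharing no exon base, only regions covering no exon of the other strand, leaving out both SCR IFNb libraries, and gene sums with exon-sharing regions. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.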

Results

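RNA bound by J2, an antibody that recognises double-stranded RNA, was sequenced from NCI-H1944 lung adenocarcinoma cells with a wild-type genotype (SCR) or an IFNAR1 knockout genotype (IFNAR1sg). IFNAR1 is a subunit of the receptor for type I interferons. Cells of each genotype had received DMSO, the MPS1 inhibitor (MPS1i), which blocks a kinase of the spindle checkpoint, or IFNb, with 2 libraries per group. The stated purpose was to find double-stranded RNA-forming transcripts that depend on type I interferon after a pulse of MPS1 inhibition. Library totals were 6801465 and 5863159 reads in SCR DMSO, 4173239 and 5835711 in SCR MPS1i, and 3842532 and 3739443 in SCR IFNb. In IFNAR1sg they were 5076497 and 7098123 in DMSO, 7147801 and 7415227 in MPS1i, and 7430687 and 6783514 in IFNb. Of all reads, 64.6% lay in regions on the strand of a gene, 20.1% antisense to a gene and 15.2% between genes, and 60.4% lay in regions in which a repeat was named.

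Both SCR IFNb libraries stood apart from the other 10. They had reads in 295367 and 296843 regions, against 566704 to 935974 in the other libraries, and 49.6% and 47.9% of their reads lay in exon-sharing regions, against 33.2% to 39.7%. Their TMM factors were 0.768 and 0.781, against 0.953 to 1.114. Without TMM factors the median change of all tested regions moved by -0.17 for MPS1i in SCR, by -0.49 for IFNb in SCR and by -0.41 for the IFNb interaction, and by under 0.1 for the other contrasts. Changes below are relative to the TMM scaling. Where a library was left out, the lone library of its group is assumed to vary like the other groups.

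**Figure D1:**
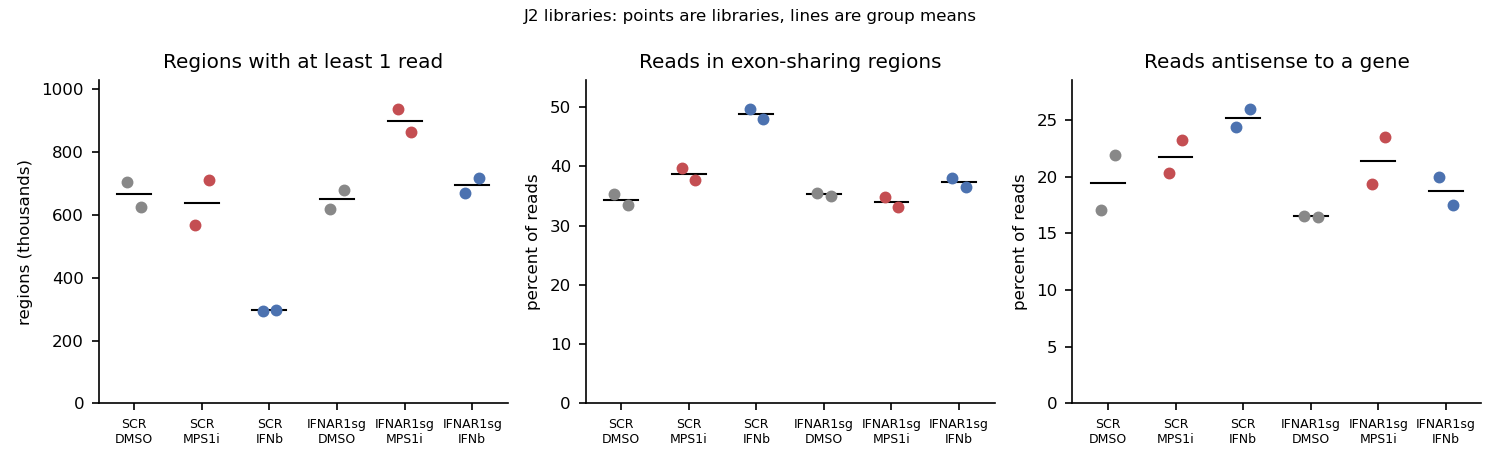
Regions with at least 1 read, percent of reads in exon-sharing regions and percent of reads antisense to a gene, by group, with points for the 12 libraries and lines for group means (n = 2). The SCR IFNb libraries had reads in 295367 and 296843 regions, fewer than each of the other 10.

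IFNAR1, the gene targeted by the guide, was followed in every library. The only IFNAR1 region with enough reads to be tested lay on chromosome 21 (33343676 to 33344099, plus strand, 1 exon base, with an AluSz6 element). It had 11.5 and 11.6 CPM (counts scaled to the library size) in SCR DMSO, 8.65 and 9.07 in SCR MPS1i, and 11.5 and 11.7 in SCR IFNb. In IFNAR1sg it had 3.33 and 2.07 in DMSO, 2.47 and 1.64 in MPS1i, and 2.84 and 1.87 in IFNb. In DMSO it was lower in IFNAR1sg than in SCR by -2.13 ± 0.37 (log2 ± SE, n = 2 per group, adjusted p = 0.0018). The call was not made with the DESeq2 Wald test (-2.11), with the DMSO groups alone (-2.13, adjusted p = 0.142) or without IFNAR1sg DMSO replicate 2 (-1.81, adjusted p = 0.266). The remaining IFNAR1 regions summed to 5.30 ± 0.06 CPM (SD) in IFNAR1sg DMSO and 6.03 ± 0.51 in SCR DMSO, a change of -0.18 ± 0.38 (adjusted p = 0.953). That sum fell with IFNb in SCR by 1.99 ± 0.55 (adjusted p = 0.00134), on 34 and 33 reads in DMSO and 8 and 0 in IFNb. It had 26 and 26 reads in SCR MPS1i, and in IFNAR1sg 24 and 33 in DMSO, 24 and 24 in MPS1i and 25 and 21 in IFNb. IFNB1, the gene of interferon beta, had 0 reads in each library. CXCL10, an interferon-induced chemokine, had 8 reads in SCR MPS1i replicate 2, 1 in SCR IFNb replicate 1 and 0 in the other 10. ISG15, an interferon-induced ubiquitin-like modifier, rose with MPS1i in SCR (1.87 ± 0.26) and IFNAR1sg (0.98 ± 0.25) and with IFNb in SCR (2.34 ± 0.26), and changed by 0.39 ± 0.26 with IFNb in IFNAR1sg (adjusted p = 0.676). CDKN1A, the cell-cycle inhibitor p21, rose with MPS1i in SCR (2.42 ± 0.27) and IFNAR1sg (2.35 ± 0.26).

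**Figure D2:**
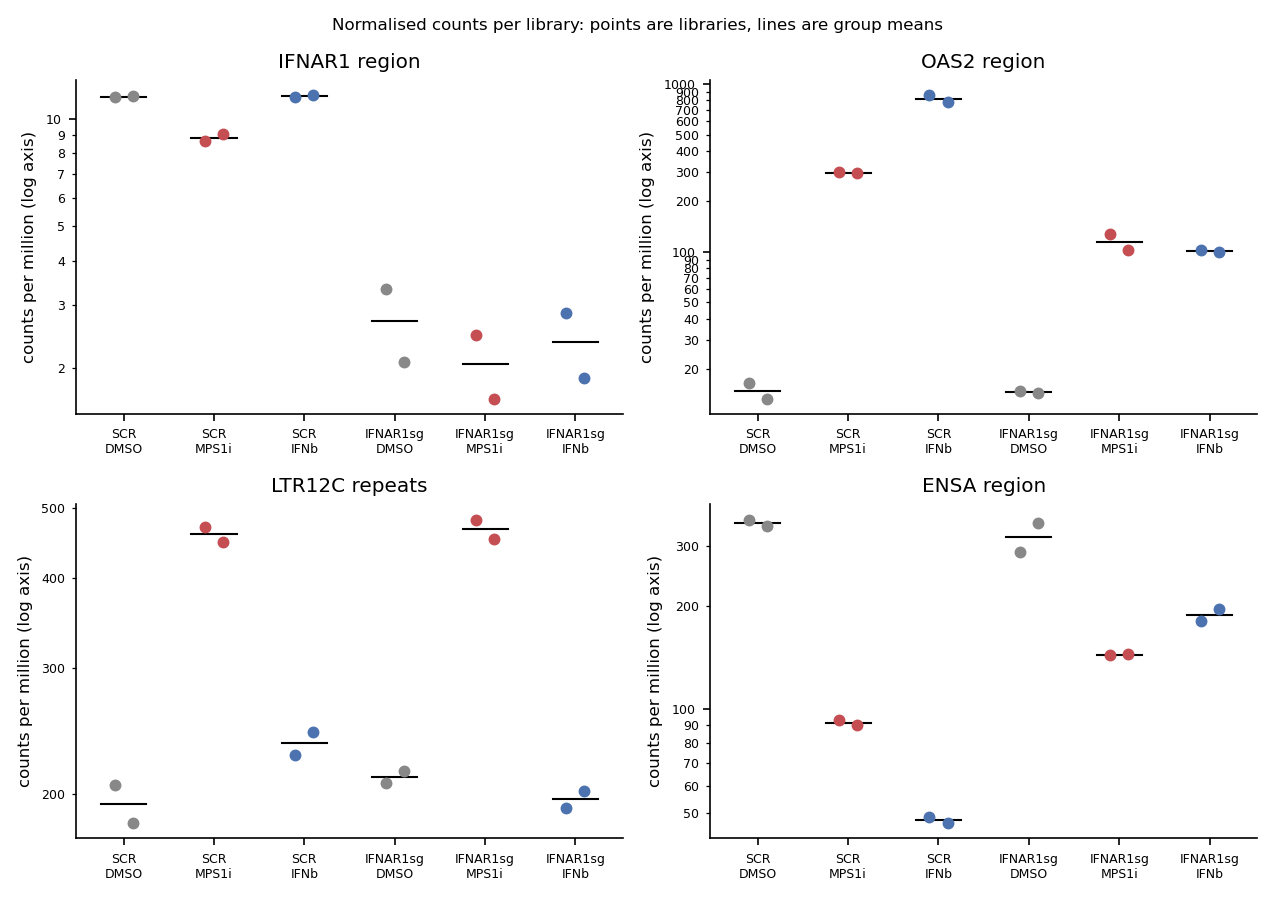
CPM (log axis, TMM scaling) of the IFNAR1 region, an OAS2 region, LTR12C repeats and an ENSA region, by group, with points for libraries and lines for group means (n = 2). The IFNAR1 region lay between 1.64 and 3.33 in all 6 IFNAR1sg libraries and between 8.65 and 11.7 in all 6 SCR libraries.

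After the MPS1i pulse in SCR cells, transcripts of antiviral genes rose in the J2 libraries. The region with the smallest p lay in OAS2, an oligoadenylate synthetase activated by double-stranded RNA (chromosome 12, 112998410 to 112999191, plus strand, 1 exon base). It rose by 4.31 ± 0.17 (log2 ± SE, n = 2 per group, adjusted p = 2.3e-34), from 14.9 to 297 CPM. Regions in RIGI (3.62 ± 0.17), a sensor of double-stranded RNA, IFI6 (3.48 ± 0.17), RMI2 (3.66 ± 0.17), IFI16 (2.96 ± 0.15), a DNA sensor, and IFI44L (3.77 ± 0.20) rose as well. RNA past the ends of some such genes rose too. It started 714 bp past RIGI and ran opposite ACO1 (3.65 ± 0.15, from 44.1 to 553), 35 bp past IFIT1 and opposite LIPA (6.79 ± 0.33), 439 bp past MX1 (4.25 ± 0.18) and 215 bp past IFI44L (4.68 ± 0.24). A region of 21:41361814 to 41410216 on the minus strand, opposite MX2, rose by 4.53 ± 0.23. It covers 13047 exon bases of the other strand.

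The regions that fell with the smallest p were mostly introns. They lay in ENSA (-1.94 ± 0.15), TXNRD1, thioredoxin reductase (-1.88 ± 0.16), the transporter gene ABCC1 (-2.02 ± 0.17), the splicing factor gene RBM39 (-2.48 ± 0.22), CCNB1, the mitotic cyclin B1 (-2.16 ± 0.20), ASS1 (-1.94 ± 0.19), PTGR1 (-1.85 ± 0.18) and PRKDC, a DNA repair kinase (-2.48 ± 0.25). Regions in the pseudogenes DUXAP10 (-1.59 ± 0.13), DUXAP8 (-1.56 ± 0.14) and DUXAP9 (-1.48 ± 0.14) fell, as did a region of the short arm of chromosome 21 (8438744 to 8439823, plus strand, 1 exon base; -1.64 ± 0.13), from 3256 to 1042 CPM. By class, antisense regions rose more often than they fell (2272 and 212 of 14389, median 0.37), as did intergenic regions (1951 and 501 of 13318, median 0.31) and exon-sharing regions (1885 and 328 of 9630, median 0.33). Without TMM factors these 3 classes had 1588 and 389 (median 0.20), 1529 and 798 (median 0.13) and 1122 and 512 (median 0.16). With library sizes set to antisense totals, which centres that class, 1047 antisense regions were higher and 605 lower (median 0.03). Intronic regions fell more often than they rose (6059 and 2399 of 51774, median -0.45). In all, 8507 of 89111 regions were higher and 7100 lower (edgeR). Without SCR DMSO replicate 1 the counts were 5128 and 4066, without SCR MPS1i replicate 1 they were 5636 and 3372, and without SCR MPS1i replicate 2 they were 4596 and 2686. Without TMM factors 5927 were higher and 9760 lower, with DESeq2 size factors 7793 and 7820 and with no filter 3064 and 3191, each of which turned the balance. The Wald test of DESeq2 gave 4425 and 3752.

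**Figure D3:**
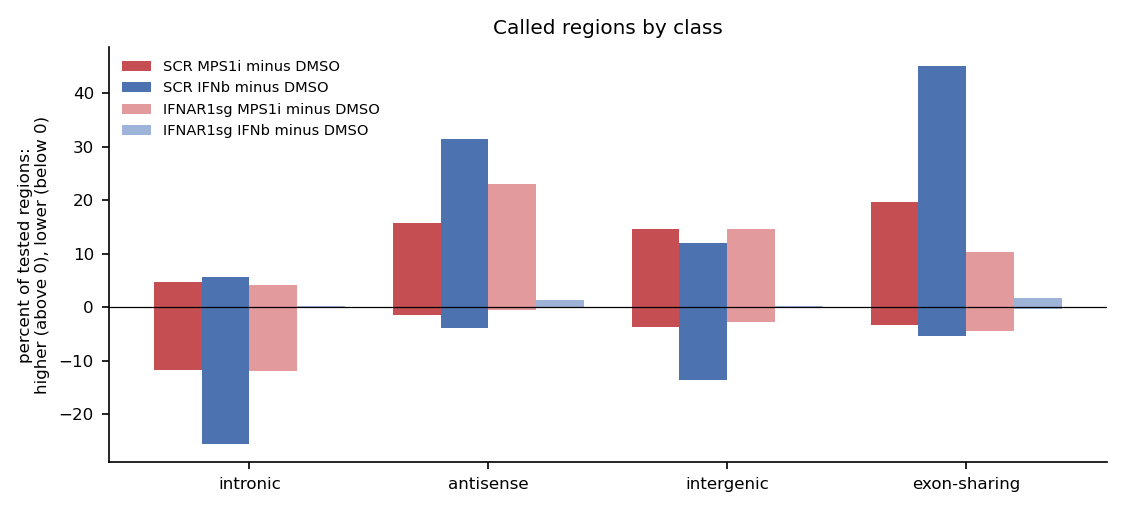
Percent of tested regions called higher (above 0) and lower (below 0) against DMSO, by region class, with bars for the 4 treatment contrasts (n = 2 per group). With IFNb in SCR 13192 intronic regions were lower and 2898 higher, and without TMM factors 21520 and 1379.

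Of the gene lists, all 55 measured interferon-stimulated genes rose with MPS1i in SCR (median 2.94, adjusted p = 8.4e-31, and adjusted p = 0.0266 with an estimated correlation; 55 adjusted over the list alone). Among them were IFIT1, which binds viral RNA (4.05 ± 0.17), TRIM14 (1.86 ± 0.09) and TRIM5, a restriction factor whose sum overlaps exons of TRIM22 on the other strand (3.51 ± 0.15). Of 20 genes of double-stranded RNA sensing and processing, 14 rose and 4 fell (14 and 5 adjusted over the list alone; adjusted p = 7.2e-04, and 0.0995 as adjusted p with an estimated correlation). Those that rose included IFIH1, the sensor MDA5 (2.73 ± 0.13), RIGI (2.70 ± 0.13), OASL (2.94 ± 0.17) and OAS1 (3.26 ± 0.19). Of 13 antigen presentation genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), among them the immunoproteasome gene PSMB9 (2.43 ± 0.21), NLRC5 (1.43 ± 0.16), HLA-F (2.98 ± 0.57) and HLA-E (2.18 ± 0.44). Of 15 NF-kB targets and cytokines 9 rose (9 adjusted over the list alone), with CXCL8 at 3.05 ± 0.27, CXCL5 at 1.57 ± 0.14 and BIRC3 at 2.20 ± 0.23. All 7 measured sums of replication-dependent histone genes rose (7 adjusted over the list alone), from 1.02 ± 0.16 for H2AC6 to 2.09 ± 0.30 for H2BC18 among the 4 with the smallest p. As gene sums leave out exon-sharing regions, the histone values here and below do not measure histone mRNA. These last 3 lists had adjusted p = 0.00168, 1.7e-04 and 3.6e-04 in that order, and each had adjusted p = 0.0995 with an estimated correlation. Of 26 p53 targets 11 rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 0.0245, and adjusted p = 0.155 with an estimated correlation; 7 and 4 without TMM factors), with BTG2 at 2.88 ± 0.42, RRM2B at 1.67 ± 0.26 and CMBL at -0.55 ± 0.10.

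Of 39 mitosis and cell-cycle genes 16 fell and 2 rose (16 and 3 adjusted over the list alone; adjusted p = 0.00188, and adjusted p = 0.300 with an estimated correlation). CCNB1 (-1.99 ± 0.16), the spindle factor TPX2 (-1.83 ± 0.16), ASPM (-1.497 ± 0.14) and the kinesin KIF11 (-1.45 ± 0.17) fell. Of 12 genes of the unfolded protein and integrated stress responses 4 rose and 4 fell (4 and 4 adjusted over the list alone), and the median was -0.52, the mean 0.24, the camera test downward (adjusted p = 0.678) and fry upward (adjusted p = 0.0494). ATF3 (2.84 ± 0.20) and DDIT3 (2.39 ± 0.20), stress-induced transcription factors, rose, and SLC7A11 (-0.97 ± 0.10) and TRIB3 (-1.74 ± 0.22) fell. Of 8 genes on the DNA sensing list 3 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.531), with SAMHD1 at 2.11 ± 0.23, ENPP1, which degrades cGAMP, at 2.01 ± 0.34 and the lamin gene LMNB1 at -1.83 ± 0.16. Of 9 genes on the list of lung epithelial markers 4 rose and 1 fell (4 and 2 adjusted over the list alone, 4 and 3 without TMM factors; median -0.08, mean 0.05, adjusted p = 0.855), with KRT8 at 0.98 ± 0.17. KEAP1, which is on that list but is not specific to epithelium, changed by -1.41 ± 0.22. Markers of other cell types were barely measured. Of 10 fibroblast markers 2 were measured and both rose (2 adjusted over the list alone), FAP by 3.62 ± 0.39 and ACTA2 by 1.38 ± 0.59. Without exon-sharing regions such sums do not measure marker mRNA, and whether RNA ran in from neighbouring genes was not tested. The ACTA2 call was lost with DESeq2 size factors (1.33), without TMM factors (1.202), with the replicate block (1.39), with exon-sharing regions in the sums (1.38) and without IFNAR1sg IFNb replicate 1 (1.37), SCR DMSO replicate 1 (1.75) or 2 (1.102) or SCR MPS1i replicate 1 (1.30) or 2 (1.497). Of 12 immune cell markers 3 were measured, of which CD8A (3.62 ± 0.89) and CD4 (2.30 ± 0.83) rose (2 adjusted over the list alone; adjusted p = 0.104). The CD4 call was lost without SCR DMSO replicate 1 (2.74) or 2 (1.998) or SCR MPS1i replicate 1 (1.85). The lists of mitochondrially encoded genes and of structured small RNAs had 0 measured members.

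**Figure D4:**
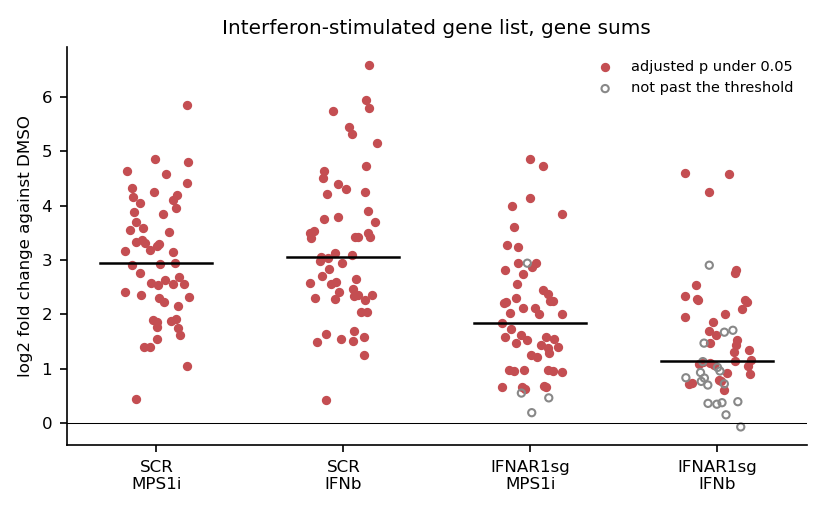
Log2 fold changes against DMSO of 55 interferon-stimulated gene sums in the 4 treatment contrasts, with points for genes (filled when past the threshold) and lines for medians (n = 2 per group). Medians were 2.94 and 1.83 with MPS1i and 3.05 and 1.13 with IFNb, in SCR and IFNAR1sg.

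Endogenous retroviral repeats also rose with MPS1i in SCR. LTR12C, a long terminal repeat of the HERV9 group, rose by 1.24 ± 0.09 (n = 2 per group), from 194 to 460 CPM, LTR12D by 2.05 ± 0.22, HERV9-int by 2.73 ± 0.29, MLT2D by 1.38 ± 0.13 and L1PB1 by 0.73 ± 0.08. The simple repeat (GGC)n rose by 1.41 ± 0.15, or by 0.88 without SCR MPS1i replicate 2, with replicates far apart (124 ± 55.3 CPM in DMSO and 328 ± 141 with MPS1i, mean ± SD). Charlie1b, a DNA transposon, fell by 1.27 ± 0.10, (TTCT)n by 1.31 ± 0.13, LTR27C by 1.60 ± 0.23, U6 by 1.18 ± 0.20, MADE1 by 0.58 ± 0.10 and HSAT5 by 1.08 ± 0.19. Of 1653 subfamilies 266 rose and 101 fell, 367 in all, or 244 without SCR MPS1i replicate 1. Of 56 families 14 rose, with ERV1 at 0.56 ± 0.06, ERVK at 0.45 ± 0.07, ERVL-MaLR and ERVL at 0.35 ± 0.06 each, Gypsy at 0.44 ± 0.08 and SVA at 0.35 ± 0.07. The 3 that fell were Alu (-0.24 ± 0.07), snRNA (-0.31 ± 0.10) and RNA (-0.99 ± 0.40). The Alu call was lost without SCR MPS1i replicate 1 (-0.17) and the snRNA call without SCR MPS1i replicate 2 (-0.26) and over regions sharing no exon base (-0.23). The RNA call was lost without any 1 of the SCR or IFNAR1sg IFNb libraries (-1.04 to -0.93), without both SCR IFNb libraries (-0.97) and over regions sharing no exon base (-0.92).

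Of the repeat lists, ERV1 had 81 of 260 subfamilies up and 6 down (89 and 6 adjusted over the list alone; adjusted p = 4.1e-08, and adjusted p = 0.0995 with an estimated correlation). Further lists past the threshold upward were LTR12 (5 of 7), HERV9 (3 of 3), HERVE with LTR2 (3 of 5, including HERVE-int at 2.06 ± 0.27), HERVK with LTR5 (3 of 4, including LTR5_Hs at 0.61 ± 0.11), THE1 (7 of 9), young L1 (8 of 8, including L1PA2 at 0.69 ± 0.08), MLT2 (6 of 12), ERVK (8 of 31), ERVL (28 up and 1 down of 106), ERVL-MaLR (30 and 2 of 76), MLT1 (21 and 2 of 52), other satellites (7 and 1 of 16, including SAR at 1.77 ± 0.22) and L1 (40 and 2 of 131). Adjusted over the list alone the members up were 5, 3, 4, 3, 8, 8, 7, 9, 28, 34, 25, 8 and 44 in that order. Camera compares a list with the other subfamilies, and the median of all 1653 was 0.13. A downward call thus means lower than the others, and the simple repeat family changed by 0.02 ± 0.06 (adjusted p = 0.800). Downward were Alu (16 down and 1 up of 51), AluJ (4 of 4), AluS (8 of 17), AluY (2 down and 1 up of 25), DNA transposons (26 down and 14 up of 213) and simple repeats (40 down and 42 up of 630). Adjusted over the list alone the members down were 22, 4, 9, 1, 23 and 33. The members up without TMM factors were 5 for ERVK, 15 for ERVL, 16 for ERVL-MaLR, 9 for MLT1, 2 for MLT2 and 21 for L1, and those down 37 for Alu, 16 for AluS, 12 for AluY, 65 for DNA transposons and 68 for simple repeats. None of these calls was made with an estimated correlation, with adjusted p = 0.0995 to 0.640. The lists not past the threshold were MER41 (3 of 7 up), SVA (3 of 6 up, including SVA_D at 0.48 ± 0.10), LTR10 (4 of 16 up), MER57 (2 of 9 up), HERVH with LTR7 (1 up and 1 down of 5), L2 (0 of 7), MIR (0 of 5), tRNA (0 of 6), snRNA (1 of 6 down) and scRNA (0 of 3). Alpha satellite (0.00 ± 0.10) and 7SL RNA (0.65 ± 0.17, adjusted p = 0.0017) had 1 member each. Without TMM factors the medians of L1 (0.16), MIR (0.02), snRNA (0.05) and scRNA (0.14) turned to -0.01, -0.15, -0.12 and -0.02.

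**Figure D5:**
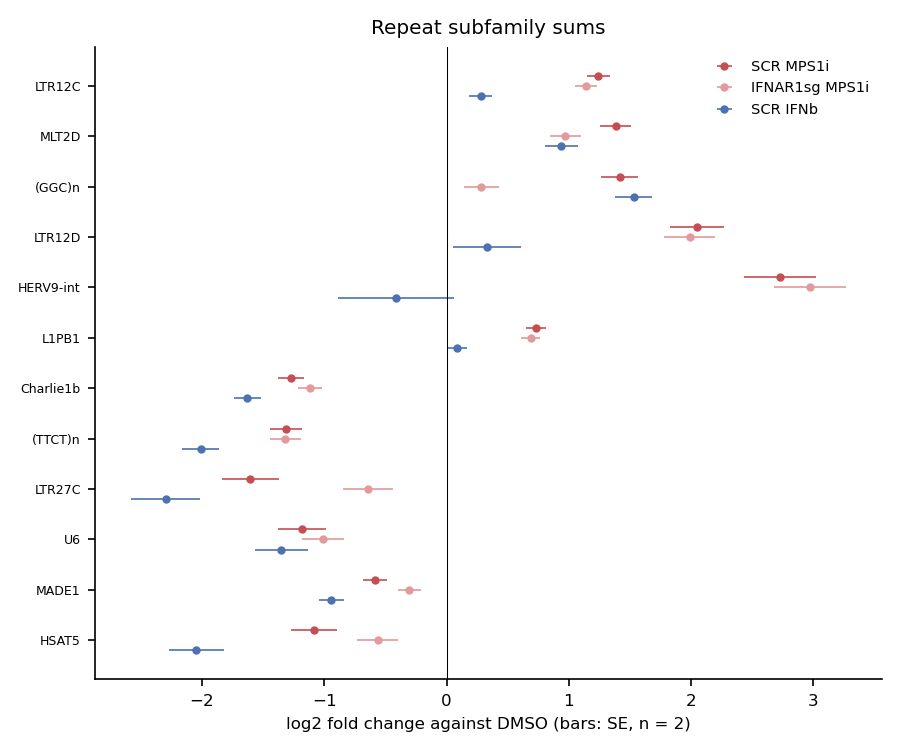
Log2 fold changes against DMSO of 12 repeat subfamily sums with MPS1i in SCR and IFNAR1sg and with IFNb in SCR, with bars for SE (n = 2 per group). LTR12C and HERV9-int rose with MPS1i by 1.24 and 2.73 in SCR and by 1.14 and 2.97 in IFNAR1sg.

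IFNb in SCR served as the direct interferon response. The same OAS2 region rose by 5.77 ± 0.18 (n = 2 per group, adjusted p = 4.0e-42), to 821 CPM. Regions in IFI6 (5.21 ± 0.17), RMI2 (5.13 ± 0.18), RIGI (4.95 ± 0.18), IFI16 (4.25 ± 0.16), MX1, an antiviral GTPase (5.47 ± 0.21), and IFIT1 (5.49 ± 0.22) rose, as did the regions opposite MX2 (6.94 ± 0.23) and past RIGI (4.60 ± 0.16). A region of TRIM5 (6.13 ± 0.22) covered exons of TRIM22 on the other strand, and a region of LIPA (5.63 ± 0.22) covered exons of IFIT2. Falls were led by RNA 10 bp past ALYREF (-2.24 ± 0.13) and 46 bp past ITGB1 (-2.41 ± 0.16), and by introns of ENSA (-2.88 ± 0.16), DUXAP10 (-2.51 ± 0.14), DUXAP9 (-2.70 ± 0.15), DUXAP8 (-2.54 ± 0.15), TXNRD1 (-2.32 ± 0.14), MBD3 (-2.63 ± 0.17, 1 exon base) and PUM3 (-2.75 ± 0.18). The locus ENSG00000266302 (-3.22 ± 0.18) and a pair of regions far from genes on chromosomes 20 (30633507 to 30651285, minus strand; -2.68 ± 0.18) and 4 (49564097 to 49579833, plus strand, 1 exon base; -3.11 ± 0.21) fell as well. These falls were measured in the pair of libraries with the fewest detected regions.

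In IFNb-treated SCR cells all 55 interferon-stimulated genes rose (55 adjusted over the list alone; median 3.05, adjusted p = 1.4e-56, and adjusted p = 0.00493 with an estimated correlation), including CMPK2 (5.80 ± 0.24) and IFIT1 (5.44 ± 0.17). Of 20 genes of double-stranded RNA sensing 13 rose and 5 fell (13 and 5 adjusted over the list alone), including IFIH1 (3.11 ± 0.13) and OAS3 (3.05 ± 0.16), and of 13 antigen presentation genes 7 rose and 1 fell (7 and 2 adjusted over the list alone; median 1.64, or 0.66 without TMM factors), including PSMB9 (4.22 ± 0.20), NLRC5 (2.37 ± 0.16), HLA-E (3.001 ± 0.43) and PSME2 (3.11 ± 0.58). Both lists had adjusted p = 0.0275 with an estimated correlation. Of 26 p53 targets 14 fell and none rose (15 and 1 adjusted over the list alone; adjusted p = 0.184), among them DDB2 (-2.001 ± 0.20), TNFRSF10B (-1.06 ± 0.12) and MDM2 (-0.84 ± 0.10), the ubiquitin ligase of p53, whose direction turned to 0.79 when exon-sharing regions were added. Of 39 mitosis genes 21 fell and 2 rose (22 and 2 adjusted over the list alone; adjusted p = 0.293), with CCNB1 at -2.02 ± 0.17 and TPX2 at -1.96 ± 0.17, the latter turning to 0.32 with exon-sharing regions. Of 12 stress-response genes 6 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.595), with SLC7A11, a cystine transporter, at -1.81 ± 0.11, PSAT1 at -2.38 ± 0.24 and PHGDH at -1.76 ± 0.30. Histone genes (3 of 7 up, 3 adjusted over the list alone), NF-kB targets (7 up and 3 down of 15, 8 and 3 adjusted over the list alone) and DNA sensing genes (4 up and 2 down of 8, 4 and 2 adjusted over the list alone) had adjusted p = 0.00171, 6.6e-04 and 0.0272, and adjusted p = 0.108, 0.159 and 0.196 with an estimated correlation. The median of the histone genes, 0.44, was -0.05 without TMM factors. Lung epithelial markers (2 up and 4 down of 9, 2 and 4 adjusted over the list alone, 1 and 6 without TMM factors) included CDH1 at -1.63 ± 0.23.

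More repeat sums fell than rose with IFNb in SCR: 655 of 1653 subfamilies fell and 99 rose, 754 in all. L1MA4A (-1.40 ± 0.10), L1MA3 (-1.19 ± 0.09), Charlie1b (-1.63 ± 0.11), (TTCT)n (-2.01 ± 0.15), AluJb (-0.81 ± 0.07) and AluJr (-0.81 ± 0.07) fell. MER57F (2.88 ± 0.30), (TTTTCC)n (2.06 ± 0.13), (CAGCC)n (3.14 ± 0.23), (CCA)n (1.88 ± 0.17) and (TAAA)n (1.73 ± 0.20) rose. LTR12C rose by 0.28 ± 0.10 (adjusted p = 0.0128) but was at -0.22 ± 0.10 without TMM factors (adjusted p = 0.0511), and HERV9-int changed by -0.41 ± 0.48. Of L1 subfamilies 100 of 131 fell and 4 rose (103 and 4 adjusted over the list alone; adjusted p = 1.5e-05, and adjusted p = 0.667 with an estimated correlation), and of Alu subfamilies 42 of 51 fell and 1 rose (44 and 1 adjusted over the list alone; adjusted p = 8.7e-04, and adjusted p = 0.667 with an estimated correlation). ERV1 subfamilies had a median of -0.50 and a fry test downward (adjusted p = 0.00253) but a camera test upward (adjusted p = 0.0855). The SVA family rose by 0.36 ± 0.07, changed by -0.13 without TMM factors and was not past the threshold with only the groups of the contrast (0.15). By region class, 13192 of 51774 intronic regions fell and 2898 rose (median -1.05), while 4514 of 14389 antisense regions rose and 551 fell (median 0.62) and 4342 of 9630 exon-sharing regions rose and 523 fell (median 0.73). Without TMM factors the latter pair had 2034 and 1360 (median 0.13) and 2219 and 1088 (median 0.24). With library sizes set to antisense totals, which centres that class, 1056 antisense regions were higher and 1615 lower (median -0.07), so the balance rests on the scaling. Of all regions 13339 were higher and 16090 lower, or 6405 and 27224 without TMM factors and 4241 and 10249 with no filter. The Wald test of DESeq2 gave 8106 lower. The lower count was 10547 without SCR DMSO replicate 1, 8163 without SCR IFNb replicate 1 and 8475 without SCR IFNb replicate 2.

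The regions that changed with MPS1i and with IFNb in SCR overlapped: 4523 were higher in both, against 1273 from the product of the counts, 5128 were lower in both, against 1282, and 152 went opposite ways. Both contrasts share the SCR DMSO libraries, so the product is not the overlap expected by chance. The covariance of the changes was 1.29, against a mean of 0.17 in 10 simulations of unchanged groups against the same controls. The correlation across regions, which are not independent replicates, was 0.566 against 0.379 simulated. The simulations drew all groups from 1 set of means, so they allow for the shared controls but not for a shift between region classes. Intronic regions fell more often than they rose in both contrasts (6059 and 2399 with MPS1i, 13192 and 2898 with IFNb). The overlap therefore does not separate such a shift from shared responses of single transcripts. The 9651 regions called alike numbered 5582 without SCR DMSO replicate 1, 5799 without SCR MPS1i replicate 1 and 4609 without SCR MPS1i replicate 2.

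MPS1i in IFNAR1sg cells asked what the pulse changed when the receptor gene had been targeted. Part of the rise was in regions that IFNb did not raise. RNA opposite RGS12 (chromosome 4, 3342934 to 3439912, minus strand, covering 10731 exon bases of the other strand) rose by 4.43 ± 0.23 (n = 2 per group, adjusted p = 1.5e-26), against 3.96 with MPS1i and -0.06 with IFNb in SCR. RNA 3216 bp past MDM2 and opposite CPM rose by 3.24 ± 0.18 (2.76 and -0.96 in SCR), 112 bp past COX6C by 3.17 ± 0.22 (2.61 and 0.01), 2349 bp past SQSTM1, an autophagy receptor, by 2.77 ± 0.19 (2.37 and -1.30), and 6418 bp past C6orf62 by 2.48 ± 0.17 (2.08 and -0.56). RNA 20 bp past LY6E rose by 4.27 ± 0.28 (4.13 and 1.22 in SCR, the latter with adjusted p = 0.00344). Regions that IFNb raised in SCR rose too, in IFI6 (3.12 ± 0.17), 439 bp past MX1 (3.41 ± 0.18), 714 bp past RIGI (2.42 ± 0.15), 215 bp past IFI44L (3.69 ± 0.24), and in ENSG00000257452 (2.60 ± 0.14), which runs opposite the OAS genes. Introns fell in ABCC1 (-2.05 ± 0.17), ASS1 (-2.13 ± 0.18), TXNRD1 (-1.75 ± 0.16), SERINC5 (-2.54 ± 0.24), CCNB1 (-2.08 ± 0.20), RIMKLB (-1.75 ± 0.18), PTGR1 (-1.64 ± 0.17), RBM39 (-1.98 ± 0.21), LDHA, lactate dehydrogenase (-2.79 ± 0.30), CPS1 (-1.67 ± 0.18), PTBP1 (-2.01 ± 0.21) and HPD (-2.11 ± 0.23).

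Of 55 interferon-stimulated genes 51 rose with MPS1i in IFNAR1sg (51 adjusted over the list alone; median 1.83, adjusted p = 1.5e-17, and adjusted p = 0.0569 with an estimated correlation), including IFIT1 (2.95 ± 0.19), TRIM5 (2.12 ± 0.16), SP110 (2.57 ± 0.20) and OASL (2.22 ± 0.17). Of the 20 double-stranded RNA sensing genes 10 rose and 4 fell (11 and 4 adjusted over the list alone; adjusted p = 0.0358, and adjusted p = 0.255 with an estimated correlation). NF-kB targets (11 of 15 up, 12 adjusted over the list alone), with CXCL8 at 2.18 ± 0.29, and histone genes (5 of 7 up, 7 adjusted over the list alone), with H2BC18 at 2.35 ± 0.31, each had adjusted p = 0.175 with an estimated correlation. Mitosis genes fell (20 down and 3 up of 39, 20 and 4 adjusted over the list alone; adjusted p = 4.0e-05, and adjusted p = 0.239 with an estimated correlation), with CCNB1 at -1.78 ± 0.15, ASPM at -1.35 ± 0.13, TPX2 at -1.248 ± 0.14 and MCM5, a replication helicase subunit, at -1.60 ± 0.19. LTR12C rose by 1.14 ± 0.09, LTR12D by 1.99 ± 0.21, HERV9-int by 2.97 ± 0.29, THE1B-int by 0.97 ± 0.10, HERVL-int by 0.93 ± 0.10 and HERVS71-int by 1.13 ± 0.13, among 362 subfamilies that rose and 67 that fell. The acro satellite family rose by 3.17 ± 0.34, with replicates far apart (19.7 ± 10.9 CPM against 2.27 ± 1.19 with DMSO, mean ± SD; 2.51 without IFNAR1sg MPS1i replicate 1), and ERV1 by 0.55 ± 0.06. In all, 8372 regions were higher and 7012 lower, or 6950 and 8259 without TMM factors, which turned the balance. With no filter there were 3931 and 2215, and with the Wald test of DESeq2 3720 and 3490. The counts were 5190 and 4208 without IFNAR1sg DMSO replicate 1, 3885 and 3157 without IFNAR1sg DMSO replicate 2, and 4397 and 3311 without IFNAR1sg MPS1i replicate 2, and the lower count was 4545 without IFNAR1sg MPS1i replicate 1. In both genotypes 4460 regions were higher, against 799 from the product, 3451 lower, against 559, and 13 opposite, with no library shared by the contrasts. Calls differed by region class in both contrasts, so the product is not the overlap expected by chance here either.

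IFNb in IFNAR1sg raised interferon-stimulated genes as well, by less. Of 55 such genes 36 rose (42 adjusted over the list alone; median 1.13, adjusted p = 7.8e-73, and adjusted p = 0.00239 with an estimated correlation), including IFIT1 (2.34, against 5.44 in SCR) and TRIM5 (2.01 against 5.73). Of 20 double-stranded RNA sensing genes 8 rose (11 up and 2 down adjusted over the list alone; adjusted p = 2.7e-13, and adjusted p = 0.0114 with an estimated correlation), and PSMB9 rose by 2.04. In all, 489 regions were higher and 117 lower, 447 and 95 of which were so in SCR too. With the replicate block there were 738 and 188, with no filter 232 and 4, and over regions sharing no exon base 310 and 49. Without TMM factors 183 were lower. The counts were 229 and 28 without IFNAR1sg DMSO replicate 2 and 180 and 18 without IFNAR1sg IFNb replicate 1. The lower count was 45 without IFNAR1sg DMSO replicate 1, and the higher count was 763 and 776 without IFNAR1sg MPS1i replicate 1 or 2 and 885 and 871 without SCR DMSO replicate 1 or 2. Of 1653 repeat subfamilies 0 rose and 1 fell (edgeR), with 142 at an unadjusted p under 0.05; no other tool was run on these sums. The number called was 0 without IFNAR1sg DMSO replicate 1 or IFNAR1sg IFNb replicate 1, 2 without SCR MPS1i replicate 2, 3 without IFNAR1sg IFNb replicate 2 or SCR DMSO replicate 2, 5 without IFNAR1sg MPS1i replicate 1 or 2 and 6 without SCR IFNb replicate 1 or 2.

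Between the genotypes in DMSO, 12 regions were higher and 57 lower in IFNAR1sg, and 45 of the 57 were antisense. With library sizes set to antisense totals, 4 antisense regions were higher and 15 lower. SCR DMSO replicate 2 had 21.9% antisense reads, against 17.02% in replicate 1 and 16.5% in each IFNAR1sg DMSO library. With the replicate block 37 and 159 regions were called, with only the groups of the contrast 0 and 1 (edgeR) and with no filter 2 and 14. Over regions covering no exon of the other strand there were 22 and 14, over those sharing no exon base 5 higher, with a filter on a mean of 10 counts 24 lower, and without both SCR IFNb libraries 21 lower. At an unadjusted p under 0.05 there were 5996 regions. No list member passed the threshold outside the simple repeats, where 1 subfamily was higher and 1 lower, with 104 of 1653 at an unadjusted p under 0.05. Each library moved these region counts. They were 91 and 880 without SCR DMSO replicate 1, 7 and 4 without SCR DMSO replicate 2, 32 and 86 without IFNAR1sg DMSO replicate 1, 0 and 18 without IFNAR1sg DMSO replicate 2, and 22 to 36 and 139 to 225 without any 1 of the other 8. Of the 2 subfamilies, 1 was called without IFNAR1sg DMSO replicate 1 and 0 without IFNAR1sg DMSO replicate 2 or SCR DMSO replicate 2.

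The MPS1i interaction asked where the SCR rise exceeded that of IFNAR1sg. It did in exon-sharing regions of IFI16 (1.34 ± 0.21, adjusted p = 2.2e-04), RIGI (1.498 ± 0.23), IFI44 (1.80 ± 0.29), PARP9 (1.35 ± 0.22), OAS2 (1.34 ± 0.23) and TRIM38 (1.35 ± 0.24), in RMI2 (1.40 ± 0.24), and in RNA 714 bp past RIGI (1.23 ± 0.20). The OAS2 gene sum, which leaves out exon-sharing regions, did not differ past the threshold (-0.59 ± 0.69, adjusted p = 0.845). Of 55 interferon-stimulated genes 21 differed, all higher in SCR (37 adjusted over the list alone; median 1.00, adjusted p = 5.7e-39, and adjusted p = 0.0140 with an estimated correlation), including TRIM14 (0.87 ± 0.12) and PLSCR1 (1.16 ± 0.21). Of 20 double-stranded RNA sensing genes 6 differed (9 adjusted over the list alone; adjusted p = 1.0e-06, and adjusted p = 0.0677 with an estimated correlation), IFIH1 by 0.94 ± 0.18, the kinase gene EIF2AK2 by 0.76 ± 0.15, OAS1 by 1.42 ± 0.28 and PNPT1 by 0.97 ± 0.20. Of 13 antigen presentation genes NLRC5 differed (0.94 ± 0.23; 3 genes adjusted over the list alone; adjusted p = 0.00142, and adjusted p = 0.0861 with an estimated correlation), and of 8 DNA sensing genes SAMHD1 (1.45 ± 0.35) and IFI16 (1.248 ± 0.30). The NLRC5 call was lost without IFNAR1sg DMSO replicate 2 (0.94) or SCR DMSO replicate 2 (0.84), and the SAMHD1 call without these (1.07 and 1.30) or SCR MPS1i replicate 2 (1.29). The IFI16 call was lost without IFNAR1sg DMSO replicate 1 (1.02, adjusted p = 0.168) or SCR MPS1i replicate 1 (1.14, adjusted p = 0.0549). No mitosis gene, p53 target or ERV1 subfamily passed the threshold, and LTR12C did not either; of all subfamilies (GGC)n (1.13 ± 0.21) and (TTTTCC)n (0.80 ± 0.19) did. (GGC)n was not past the threshold without IFNAR1sg DMSO replicate 2 (0.55), SCR DMSO replicate 2 (0.74) or SCR MPS1i replicate 2 (0.56), and was at 1.70 without SCR DMSO replicate 1. (TTTTCC)n was not past it without TMM factors (0.72 ± 0.20, adjusted p = 0.123), nor without any 1 of the DMSO or SCR MPS1i libraries or IFNAR1sg MPS1i replicate 2 (0.68 to 0.84). The number called was 1 without IFNAR1sg DMSO replicate 1, SCR DMSO replicate 1 or SCR MPS1i replicate 1, 0 without IFNAR1sg DMSO replicate 2, SCR DMSO replicate 2 or SCR MPS1i replicate 2, and 4 without IFNAR1sg MPS1i replicate 1 or 2. In all, 46 regions were higher and 10 lower, 36 of the 46 exon-sharing, against 6033 regions at an unadjusted p under 0.05. The counts depended on the processing: they were 143 and 25 with the replicate block, 0 and 6 with no filter (edgeR), 86 and 6 with the Wald test of DESeq2 and 22 and 4 with only the groups of the contrast. They were 7 and 7 over regions sharing no exon base and 154 and 35 over regions covering no exon of the other strand, and without both SCR IFNb libraries 5 were lower. The higher count was 77 and 78 without IFNAR1sg IFNb replicate 1 or 2, 94 without IFNAR1sg MPS1i replicate 1 and 175 without SCR DMSO replicate 1. The lower count was 16 without IFNAR1sg DMSO replicate 1, 25 without IFNAR1sg IFNb replicate 1 or 2, 70 without IFNAR1sg MPS1i replicate 1, 212 without SCR DMSO replicate 1, 5 without SCR DMSO replicate 2, 17 without SCR IFNb replicate 1 or 2 and 21 without SCR MPS1i replicate 2.

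The IFNb interaction was larger. Regions in RIGI (3.26 ± 0.23, adjusted p = 4.8e-18), OAS2 (2.98 ± 0.24), TRIM38 (2.95 ± 0.24), RMI2 (2.84 ± 0.24), IFI16 (2.74 ± 0.21), APOL2 (2.59 ± 0.23) and SPP1, the secreted protein osteopontin (1.98 ± 0.16), rose more in SCR. The OAS2 gene sum, which leaves out exon-sharing regions, rose by 4.25 ± 0.34 in SCR and 4.24 ± 0.44 in IFNAR1sg. Its interaction was not past the threshold (adjusted p = 0.984). Of 55 interferon-stimulated genes 43 differed (45 adjusted over the list alone; median 1.69, adjusted p = 8.5e-40, and adjusted p = 0.0132 with an estimated correlation), including TRIM5 (3.72 ± 0.24) and DDX60L (1.91 ± 0.19). Of 13 antigen presentation genes 5 differed (5 adjusted over the list alone; median 1.54, or 0.83 without TMM factors; adjusted p = 1.5e-05, and adjusted p = 0.0399 with an estimated correlation), NLRC5 by 1.80 ± 0.23 and PSMB9 by 2.18 ± 0.39. Double-stranded RNA sensing genes went both ways (9 up and 5 down of 20, 9 and 5 adjusted over the list alone; adjusted p = 2.7e-05, and adjusted p = 0.0647 with an estimated correlation), with OAS1 at 2.47 ± 0.29 and DHX9, an RNA helicase, at -1.75 ± 0.22, which turned to 0.65 with exon-sharing regions. Histone genes differed in 4 of 7 (4 adjusted over the list alone, 2 without TMM factors; adjusted p = 1.5e-04, and adjusted p = 0.0584 with an estimated correlation). Introns fell more in SCR: 5254 of 51774 intronic regions were lower and 796 higher, and 350 subfamilies were lower and 49 higher, AluJb by -0.76 ± 0.09. In all, 4553 regions were higher and 6294 lower, or 446 and 4053 with no filter and 1777 and 12258 without TMM factors, where the median of antisense regions turned from 0.37 to -0.05. The Wald test of DESeq2 gave 2469 lower, and over regions sharing no exon base 2825 were higher. The higher count was 2893 without IFNAR1sg DMSO replicate 2, and the counts were 2781 and 3771 without IFNAR1sg IFNb replicate 2, 2643 and 2848 without SCR IFNb replicate 1 and 2832 and 3121 without SCR IFNb replicate 2. The lower count was 4188 without SCR DMSO replicate 1.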

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

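Of the tests in this part, those on the SCR IFNb libraries, on the interferon response of IFNAR1sg and on reads from the wrong strand were chosen only after the result was seen, and the other tests on antisense regions before.

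Differences between the genotypes in the response to MPS1i were singled out because the interaction test of the difference itself passed its threshold (n = 2 per group). It did for 46 regions that rose more, or fell less, in SCR and for 10 that did the reverse, and the interferon-stimulated genes had a median difference of 1.00. The named regions higher in SCR included those in IFI16 (1.34), RIGI (1.498), IFI44 (1.80), PARP9 (1.35), OAS2 (1.34), TRIM38 (1.35) and RMI2 (1.40), and past RIGI opposite ACO1 (1.23). Also higher in SCR were ANXA1, a phospholipid-binding protein (1.12, from 1.29 in SCR and 0.17 in IFNAR1sg), the proteasome gene PSMA3 (1.47, from 1.33 and -0.15) and the ribosomal protein gene RPL13A (1.05, from 0.66 and -0.39). The named regions lower in SCR were an intron of C3orf49 (-3.12) and regions opposite TNRC6B (-1.33), COLGALT1 (-1.21), DTWD1 (-2.71) and MPP7 (-4.68). That in RPL13A was lost without IFNAR1sg DMSO replicate 2 (0.67, adjusted p = 0.350), and those in C3orf49 (-2.51, adjusted p = 0.113) and opposite COLGALT1 (-0.78, adjusted p = 0.446) without SCR DMSO replicate 2. The call opposite DTWD1 was lost without any 1 of 5 libraries (-2.83 to -2.24) and that opposite MPP7 without any 1 of 6 (-5.44 to -4.06). The Wald test of DESeq2 did not call the regions of C3orf49, DTWD1 and MPP7, and with only the groups of the contrast those of COLGALT1, DTWD1 and MPP7 were not called. A filter on a mean of 10 counts lost DTWD1 and MPP7, as did keeping only regions sharing no exon base. Leaving out both SCR IFNb libraries lost COLGALT1 and MPP7, and no filter lost TNRC6B, COLGALT1 and MPP7. With the replicate block 143 and 25 regions differed, with no filter 0 and 6 (edgeR), with the Wald test of DESeq2 86 and 6, and over regions sharing no exon base 7 and 7. Leaving out single libraries moved the 46 to between 32 and 175 and the 10 to between 5 and 212, and the lone library left in a group is assumed to vary like the other groups.

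Differences in the response to IFNb were singled out by the same interaction test. They comprised 4553 regions higher and 6294 lower, with median differences of 1.69 for interferon-stimulated genes and 1.54 for antigen presentation genes (0.83 without TMM factors). Without TMM factors the counts were 1777 and 12258, and with no filter 446 and 4053. The named regions higher in SCR included those in RIGI (3.26), OAS2 (2.98), TRIM38 (2.95), RMI2 (2.84), IFI16 (2.74), APOL2 (2.59), SPP1 (1.98) and LIPA over exons of IFIT2 (4.13), past RIGI (2.78), and opposite AFAP1 (3.21) and AIDA (2.85). The named regions lower in SCR lay in TXNRD1 (-2.19), ENSA (-2.12), AKR1C3, an aldo-keto reductase (-2.66), PUM3 (-2.24), ABCC1 (-2.28), MBD3 (-2.04), TTC5 (-2.71), SLC7A11 (-2.42), JOSD1 (-2.11), DUXAP9 (-1.85) and ENSG00000266302 (-2.37), and past ALYREF (-1.89). The 6294 fell to 2848 without SCR IFNb replicate 1, to 3121 without replicate 2, to 3771 without IFNAR1sg IFNb replicate 2 and to 4188 without SCR DMSO replicate 1. The 4553 fell to 2643, 2832 and 2781 in the first 3 of these and to 2893 without IFNAR1sg DMSO replicate 2.

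The lower intronic regions behind many of these differences lay in the SCR IFNb libraries, which also had the fewest detected regions. Smaller libraries were argued against: after drawing every library to 3739443 reads, the lowest of the other 10 still had 1.61 times as many regions as the higher of that pair. Scaling by a few strongly induced transcripts would move the intronic and exon-sharing sums of a gene alike. A gap between them within genes therefore argued against scaling as the source of that gap. How far introns fell was not settled by it, as the median of intronic regions was -1.05 with TMM factors and -1.53 without. Over 3800 genes outside the interferon list, intronic sums changed relative to exon-sharing sums by a median of -1.39 (-1.43 to -1.34) with IFNb in SCR. The same median was -0.17 (-0.18 to -0.16) with IFNb in IFNAR1sg, so different handling of that pair of libraries and a response that needs the receptor cannot be told apart, as each group has only its own pair of libraries.

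Interferon-stimulated genes also rose with IFNb in IFNAR1sg. Carry-over of RNA from the SCR IFNb samples alone would give 1 ratio of the rises for all 55 genes, if those libraries measured every gene alike. The ratios differed, with a chi-square of 13.4 per degree of freedom (54 degrees of freedom, p = 2.3e-117). Over the exon-sharing reads of 27 of these genes the chi-square was 7.98 per degree of freedom (p = 3.3e-30). A share of cells that kept a working IFNAR1 and responded as SCR cells do would also give 1 ratio under that condition. With IFNb in SCR, however, intronic sums changed relative to exon-sharing sums unevenly between genes. Over 3800 genes outside the interferon list the quartiles of that change were -1.94 and -0.75. The condition may thus not hold, so the spread of the ratios decides neither explanation. The median ratio was 20.003% (quartiles 11.4 and 30.3). Weaker signalling was not tested, as no value here separates cells.

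Antisense and intergenic regions rose more often than they fell with MPS1i in both genotypes. Antisense reads made up 20.3% and 23.2% of the SCR MPS1i libraries and 17.02% and 21.9% of the SCR DMSO libraries, so these groups overlapped. In IFNAR1sg they made up 19.4% and 23.5% with MPS1i and 16.5% in each DMSO library. In IFNAR1sg 3318 antisense regions were higher and 86 lower, as were 1951 and 370 intergenic regions. With library sizes set to antisense totals, which centres that class, 946 and 573 antisense regions were called in IFNAR1sg (median 0.06). Reads running up to 10 kb past gene ends were argued against as the whole source, since 9.29% of 17399 regions farther away were raised in both genotypes too. Within that distance the share was 10.7% of 10308. The ratio of 1.15 (1.07 to 1.24) was taken over genes whether or not they changed, so a part played by such reads stays open. Longer read-through was not tested. Reads from the wrong strand stayed open. Antisense regions called higher in IFNAR1sg rose in the SCR libraries by a median of 0.42 (0.37 to 0.45) more than the regions opposite them (2362 regions). Those called higher in SCR rose in the IFNAR1sg libraries by 0.66 (0.61 to 0.72) more (1456 regions), and only this second median passed the limit set for arguing against them. More antisense reads per library stayed open, as 37.7% of 1517 regions were still called in both genotypes with library sizes set to antisense totals. No biological explanation was tested.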

How the results depend on the processing

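The alternatives on exon bases, on exons of the other strand, on gene sums with exon-sharing regions and on leaving out both SCR IFNb libraries were chosen after seeing the data, and the others before the data were examined. Counts are given as higher and lower regions unless said otherwise.

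With DESeq2 size factors in the edgeR fit, all region, subfamily, list and overlap counts stayed within 1.5 times those reported, and all 113 named region results kept their direction and side of the threshold. They did so too without TMM factors and with the replicate block. Of 178 called gene sums, 177 did so with DESeq2 size factors and 177 with the replicate block, as did all 85 repeat sums under both.

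With no filter, where many more regions were tested, the counts were 3064 and 3191 for MPS1i in SCR, 3931 and 2215 for MPS1i in IFNAR1sg, 232 and 4 for IFNb in IFNAR1sg, 2 and 14 between genotypes, 0 and 6 for the MPS1i interaction and 446 and 4053 for the IFNb interaction. For IFNb in SCR they were 4241 and 10249. Why these counts were lower was not tested. A filter on a mean of 10 counts gave 24 lower between genotypes. Of the 113 named region results, 17 were no longer past the threshold with no filter and 2 with a mean of 10 counts.

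With the DESeq2 Wald test the counts were 4425 and 3752 for MPS1i in SCR, 3720 and 3490 for MPS1i in IFNAR1sg and 86 and 6 for the MPS1i interaction, with 8106 lower for IFNb in SCR and 2469 lower for the IFNb interaction. The IFNAR1 region was at -2.11 and was not called. With this test, regions left without an adjusted p by the default filter of DESeq2 also counted as not called. The cause was not tested.

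Without TMM factors the counts were 6405 and 27224 for IFNb in SCR and 1777 and 12258 for the IFNb interaction, 183 regions were lower with IFNb in IFNAR1sg, and subfamilies numbered 5 for IFNb in IFNAR1sg, 1 for the MPS1i interaction and 772 for the IFNb interaction. SVA repeats reversed, to -0.13 for IFNb in SCR and -0.091 for the IFNb interaction. For IFNb in SCR and its interaction this setting drops the TMM factors of 0.768 and 0.781 of the SCR IFNb libraries. For the other results the cause was not tested. Another 7 of 178 called gene sums were no longer past the threshold.

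A fold limit of 1 on the log2 scale left 275 and 45 regions for IFNb in IFNAR1sg and 5 and 27 between genotypes, fewer by construction. With the replicate block there were 738 and 188 regions and 2 subfamilies for IFNb in IFNAR1sg, 37 and 159 regions between genotypes and 143 and 25 for the MPS1i interaction. With only the groups of the contrast there were 10 subfamilies for IFNb in IFNAR1sg, 0 and 1 regions and 0 subfamilies between genotypes and 22 and 4 regions for the MPS1i interaction, and the IFNAR1 region was at -2.13 (adjusted p = 0.142). The cause was not tested.

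Of only the regions sharing no exon base, 310 and 49 were called for IFNb in IFNAR1sg, with 3 subfamilies, and 5 were higher between genotypes, 7 for the MPS1i interaction and 2825 for the IFNb interaction. Of only the regions covering no exon of the other strand, 22 and 14 were called between genotypes and 154 and 35 for the MPS1i interaction. Without both SCR IFNb libraries there were 5 subfamilies for IFNb in IFNAR1sg, 21 lower regions between genotypes and 5 for the MPS1i interaction. The cause was not tested.

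Adding exon-sharing regions to gene sums reversed LMNB1 (0.56 for IFNb in SCR and 0.42 for the interaction), TPX2 (0.32 and 0.034), DHX9 (0.65 for the interaction), MDM2 (0.79 for IFNb in SCR) and TRIB3 (0.074 for IFNb in SCR), by its own construction, since exon-sharing and intronic regions of a gene moved apart. Another 5 of 178 called gene sums were no longer past the threshold.

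Of the fixed lists, camera with an estimated correlation called 1 for MPS1i in SCR, 3 for IFNb in SCR, 1 for the MPS1i interaction and 2 for the IFNb interaction, against 27, 14, 3 and 15. In IFNAR1sg it called 0 for MPS1i and 2 for IFNb, against 25 and 8. The fry test called 32 for IFNb in SCR and 25 for the IFNb interaction. The cause was not tested.

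Leaving out each library in turn, with the lone library of a group assumed to vary like the other groups, gave these ranges. For MPS1i in SCR they were 4596 to 8974 higher, 2686 to 7547 lower and 244 to 386 subfamilies, for IFNb in SCR 8163 to 16936 lower, and for MPS1i in IFNAR1sg 3885 to 9371 higher and 3157 to 7361 lower. For IFNb in IFNAR1sg they were 180 to 885 higher, 18 to 157 lower and 0 to 6 subfamilies, and between genotypes 0 to 91 higher, 4 to 880 lower and 0 to 2 subfamilies. For the MPS1i interaction they were 32 to 175 higher, 5 to 212 lower, 0 to 4 subfamilies and 3 to 5 lists, and for the IFNb interaction 2643 to 4786 higher, 2848 to 6732 lower and 9 to 16 lists. The overlap of MPS1i and IFNb calls ranged from 4609 to 9995 and the IFNAR1 region from -2.50 to -1.81, where the call was lost without IFNAR1sg DMSO replicate 2. Among these results 56 for called gene sums were no longer past the threshold and 2080 were, against 14 and 1342 for named regions and 32 and 988 for repeats.

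Depth limits the regions that can be tested: 89111 of 5254113 passed the filter, and 46.1% of regions had no read in any library.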

Other observations

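The test results reported in this part were not planned for these features, which were chosen after their values were seen.

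Mitochondrial RNA, which can pair across its strands, was tested among the other regions but is not named above. The region covering the minus strand had 3503 CPM in SCR DMSO, 3295 in SCR MPS1i and 1939 in SCR IFNb, and 3421, 3121 and 1938 in IFNAR1sg (means, n = 2). It fell with IFNb by 0.85 ± 0.11 in SCR (adjusted p = 5.7e-10) and by 0.82 ± 0.11 in IFNAR1sg (adjusted p = 5.8e-08). With MPS1i it changed by -0.09 ± 0.11 in SCR and -0.13 ± 0.11 in IFNAR1sg, neither past the threshold. The interaction for IFNb was -0.03 ± 0.15 (adjusted p = 0.908). Without TMM factors the falls with IFNb were 1.34 ± 0.10 and 0.89 ± 0.10 and the interaction -0.45 ± 0.14 (adjusted p = 0.0166), and the change with MPS1i in SCR was -0.26 ± 0.10 (adjusted p = 0.0464).

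The plus strand was not tested against the minus strand. Its region from 0 to 877, at 7.78 CPM in SCR DMSO, passed the threshold in no contrast (0.80 ± 0.31 with MPS1i in SCR, adjusted p = 0.0599). The region from 2746 to 16569 rose with MPS1i by 0.85 ± 0.10 in SCR and 0.38 ± 0.10 in IFNAR1sg (8747 ± 2193 CPM against 6720 ± 151 with DMSO, mean ± SD), and with IFNb by 0.47 ± 0.10 in SCR, and fell with IFNb in IFNAR1sg by 0.54 ± 0.10 (adjusted p = 3.4e-04). Its IFNb interaction was 1.02 ± 0.14 (adjusted p = 1.4e-07) and its MPS1i interaction 0.47 ± 0.14 (adjusted p = 0.317). Without IFNAR1sg MPS1i replicate 1 its rise with MPS1i in IFNAR1sg was 0.14 and not past the threshold (adjusted p = 0.444), and the interaction was 0.72 and past it (adjusted p = 8.2e-04). Without IFNAR1sg MPS1i replicate 2 that rise was 0.60, and without SCR DMSO replicate 1 the interaction was 0.56 (adjusted p = 0.00988). The lone library left in a group is assumed to vary like the other groups. Without TMM factors its change with IFNb in SCR was -0.02 ± 0.09 (adjusted p = 0.863) and its IFNb interaction 0.59 ± 0.13 (adjusted p = 5.4e-04). The region from 888 to 2589 rose with MPS1i by 1.12 ± 0.10 in SCR and 0.67 ± 0.10 in IFNAR1sg (12601 and 8256 CPM in the 2 replicates, against 5979 and 7102 with DMSO), or by 0.37 in IFNAR1sg without MPS1i replicate 1 (adjusted p = 0.00762), and with IFNb by 0.68 ± 0.10 in SCR, and changed by -0.23 ± 0.10 with IFNb in IFNAR1sg (adjusted p = 0.454). Its change with IFNb in SCR was 0.19 ± 0.09 without TMM factors and not past the threshold (adjusted p = 0.0952). The IFNb interaction of this region was 0.92 ± 0.14 (adjusted p = 3.6e-06), or 0.50 ± 0.13 without TMM factors. Its MPS1i interaction was 0.45 ± 0.14 (adjusted p = 0.422), or 0.75 and 0.19 without IFNAR1sg MPS1i replicate 1 or 2.

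Within genes, intronic sums changed relative to exon-sharing sums by a median of -0.57 (-0.60 to -0.54) with MPS1i in SCR and -0.30 (-0.32 to -0.28) with MPS1i in IFNAR1sg, over 3800 genes outside the interferon list. The difference was in that direction in 79.4% and 69.3% of these genes.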
